A study of Glycine max with 12 samples.

How the data were processed

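Labelled cRNA of 12 leaf samples, made from 3.5 µg of RNA extracted from about 80 mg of tissue, was hybridised to single-colour Affymetrix Soybean Genome Arrays. The deposited series matrix holds log2 values that were made with RMA per the submitters' processing notes, which give no version. RMA corrects the background, gives all arrays of a run the same distribution by quantile normalization, and summarises the probes of a probe set by median polish. The table has 61170 probe sets, and all 12 columns were used. Numbers of exactly equal values between arrays were counted, since arrays normalized in 1 run can share values. They occurred within the 6 control arrays and within the 6 LCO arrays and hardly ever between them (2 over 36 pairs), so that the sprays appear to have been normalized in separate runs. The values of a spray are therefore on a scale of their own, and a difference between sprays holds any difference between the runs. Scanner files were not used here.

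The arrays were grouped by spray and time from the labels, as control and LCO at 0 h and 48 h, with 3 replicates in each group. The labels do not say whether replicates came from separate plants or pools, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision: the median SE of a log2 difference was 0.13, which gives a 95% interval of ± 0.28, and that of the interaction was 0.18, with ± 0.40.

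The array carries 37593 soybean probe sets, 15820 of Phytophthora sojae, 7530 of Heterodera glycines and 135 control probe sets. The soybean probe sets were tested, and the pathogen probe sets served as a measure of background. Gene names came from the platform annotation, updated through gene IDs against a RefSeq table (assembly Glycine_max_v4.0, names only), in which the IDs of 8652 of 9047 annotated probe sets were found. Of the soybean probe sets 8677 had 1 symbol, 370 several and 28546 none here, and no gene was named from a probe set with several. The 8677 probe sets cover 6031 genes, of which 1131 have an informative symbol or synonym.

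Group means were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the deposited values, with all 4 groups in 1 fit, 8 residual degrees of freedom and 11.9 with the prior. The 5 contrasts were 48 h against 0 h in control and in LCO leaves, LCO against control at 48 h and at 0 h, and the interaction of spray and time. Tests were two-sided, with Benjamini-Hochberg adjustment over the soybean probe sets and calls at an adjusted p under 0.05. Values of a single measure, such as the median of an array, were compared by exact permutation tests, two-sided, for which 3 against 3 arrays allow no p below 0.1.

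Gene lists were tested with limma's camera against the other genes with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 34 lists, with 1 probe set per gene (that with the highest mean). Of 35 lists planned before the data were examined, by gene descriptions, 4 had no counterpart once the annotation was found to hold symbols alone. The rest were restated by symbol, some with a wider or narrower scope, 4 pairs of them were merged and 7 families were added, all before any groups were compared. The merged pairs were disease resistance with salicylic acid, photosystem with Calvin cycle, reactive oxygen scavenging with class III peroxidases, and UDP-glycosyltransferases with terpenoid synthesis. With the estimated correlation no list (0) passed in any contrast by camera, where with the preset correlation 3, 0, 5, 9 and 2 passed for LCO against control at 48 h and at 0 h, control leaves, LCO leaves and the interaction. At an unadjusted p under 0.05 with the preset correlation these were 8, 8, 9, 13 and 8. Ranges of a list's adjusted p over its alternatives leave out the estimated correlation, whose result is given separately.

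Named genes were chosen by a rule set before the data were examined. They are the probe sets of 1 gene with an informative name that passed the test, with values of the groups that do not overlap, the largest changes first, each gene by its probe set with the smallest p. For the contrasts over time and at 48 h 12 were taken in each direction and for the other contrasts 8, filled up to 6 by the smallest p where fewer passed. Up to 4 members of each list with the smallest p, at 48 h between sprays and over time in control leaves, were added. Members were picked in the same way over time in LCO leaves and for the interaction, which the rule did not name. List members are represented by the probe set with the highest mean. The text describes only part of the genes so chosen.

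Replicate numbers in the labels are shared by all groups, so their pairing was checked on the deviations from the group means. Same-numbered control arrays at 0 h and 48 h deviated together (r = 0.162, 0.209 and 0.364), which counts as pairing for the change in control leaves. The other groups did not meet that rule of r over 0.1 in every pair. Fits with the replicate number as a block were run as alternatives.

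The other alternatives were a filter on dim probe sets, all probe sets in the adjustment, quantile normalization over soybean probe sets, median centring, only the groups compared, a variance prior with trend and robust estimation, array weights, leaving out each array in turn, thresholds of fold and unadjusted p, and leaving out probe sets prone to cross-hybridisation. The procedure was tested on simulated data in which 67 of 37593 probe sets changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each contrast. At 2-fold it recovered 94.0% in control leaves, 83.6% in LCO leaves, 86.6% and 94.0% between sprays at 48 h and 0 h and 58.2% of interactions, with 4 to 9 false calls. The simulated noise of a probe set had the same spread in all groups. Differences among the contrasts of 3 against 3 arrays therefore come from the random draw and do not show unequal sensitivity. Bounds on folds over the background limit were added after the results were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.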

Results

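Leaf RNA of soybean (Glycine max, cultivar OAC Bayfield) was measured on 12 Affymetrix Soybean Genome Arrays. Plants raised at 25 °C spent 5 days at 15 °C, a temperature below the optimum of the crop, before the spray on day 17. The spray, 2 mL on the first trifoliolate leaf, held either 1e-07 M of a lipo-chitooligosaccharide (LCO) or no LCO. LCOs are the Nod factors by which rhizobia signal to legume roots, and the one used here came from Bradyrhizobium japonicum. By the treatment protocol both sprays contained 0.02% Tween 20, while the label of the control samples gives distilled water. Leaves were collected directly after the spray (0 h) or 48 h later, which gave 4 groups of 3 arrays, and the number of arrays limits the precision. The series title asks how foliar LCO alters leaf transcript levels at a suboptimal temperature. The comparisons here are the change from 0 h to 48 h after each spray, the difference between these changes, and the level of LCO leaves against control leaves at each time.

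Arrays of a group correlated with each other at r = 0.990 to 0.996 across probe sets, and no array was a copy of another. The first principal component of the soybean probe sets held 45.1% of the variance and separated the times, and the second held 24.7% and separated the sprays. Pairs of control arrays shared 140 to 229 exactly equal values among 61170 probe sets, and pairs of LCO arrays shared 53 to 176. Pairs of 1 control and 1 LCO array shared 0 or 1, so the control and LCO arrays appear to come from separate normalization runs. The spray and the run cannot be told apart in any level set across them, whereas each change over time lies within a run. A probe set was taken as above background where it exceeded the 95th percentile of the pathogen probe sets of that array, a limit of 4.17 to 4.47. Where no array of the dimmer group did, the fold is given as at least that over the limit, and the log2 value beside it is the measured difference. Such a bound is taken from group means and makes no allowance for the spread between arrays.

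**Figure D1:**
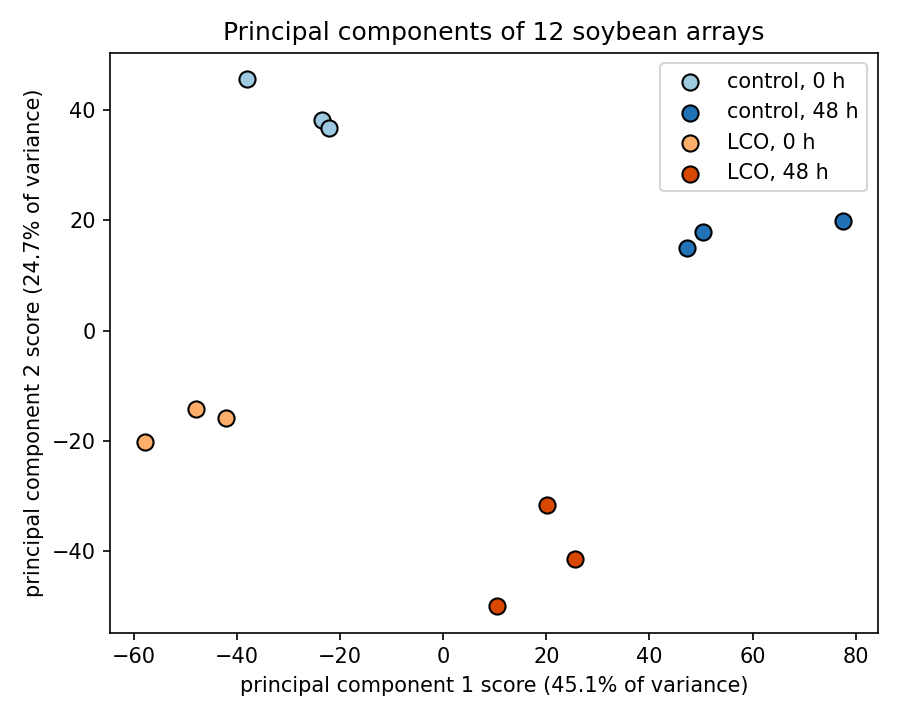
Scores of the 12 arrays on the first principal component (x axis, 45.1% of the variance) and the second (y axis, 24.7%), each point an array coloured by spray and time. The 0 h arrays lie between −57.7 and −22.0 on the x axis and the 48 h arrays between 10.5 and 77.4, and on the y axis all control arrays lie above all LCO arrays.

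In control leaves the β-1,3-glucanase gene SGlu5 (LOC547748) rose from 0 h to 48 h by 3.80 ± 0.35 on the log2 scale (13.9-fold, SE, n = 3 and 3, limma adjusted p = 7.48e-05). The PR-10 gene SAM22 rose at least 8.71-fold (measured log2 3.73 ± 0.41). The prenyltransferase gene PT01, whose product acts in glyceollin synthesis, rose 11.9-fold (3.58 ± 0.36), from a level above background on 1 of 3 arrays. The auxin-downregulated gene ADR11 fell 18.0-fold (log2 −4.17 ± 0.37, adjusted p = 6.78e-05), and the ACC synthase gene ACS1, whose enzyme makes the precursor of ethylene, at least 7.21-fold (−3.52 ± 0.23, 1e-05). Over the 37593 soybean probe sets, 3353 rose and 3439 fell, and of these 610 and 792 changed at least 2-fold. The median log2 difference was 0.02 and the median SE 0.13. Without control 0 h replicate 3 the count of 6792 fell to 4029, and without control 48 h replicate 2 to 3120, and it was 3496 when only the groups compared were fitted.

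Of the 46 genes of isoflavonoid and phenylpropanoid synthesis, 21 rose in control leaves, 2 fell and 23 did not pass the test, and 27 passed when adjusted over the list alone. Besides PT01, the chalcone synthase gene CHS8 rose 5.71-fold (log2 2.51 ± 0.25, adjusted p = 0.000155, and log2 0.92 by a dimmer probe set) and the isoflavone synthase gene IFS2 5.24-fold (2.39 ± 0.28, 0.000381). The dirigent protein gene DIR22 rose 4.23-fold (2.08 ± 0.18), and PTS-L5 and PTS-L4, which are on no list, rose at least 3.26-fold and 3.08-fold. The list stood above the other genes by camera (adjusted p = 6.81e-07), but not with the correlation of its members estimated from the data (adjusted p = 0.460 with an estimated correlation). The lists were restated by gene symbol after the annotation was seen and before any groups were compared.

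Among the 16 genes of pathogenesis-related proteins, 7 rose, 2 fell and 7 did not pass in control leaves, with 9 passing when adjusted over the list alone. The chitinase genes CHIA1 and chib1-a (LOC100815291) rose 4.74-fold, from above background on 1 of 3 arrays, and at least 1.62-fold beside SGlu5 and PR-10, while another glucanase gene, SGlu2 (LOC547822), fell 4.71-fold (log2 −2.23 ± 0.49, adjusted p = 0.0103). It was 2.79-fold without control 48 h replicate 2. The fall of SGlu2 did not pass when only the groups compared were fitted (adjusted p = 0.0553, in a range of 0.00326 to 0.0553). As a set the list did not pass (camera adjusted p = 0.0554, and adjusted p = 0.549 with an estimated correlation).

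Of 38 glutathione S-transferase genes, which encode detoxification enzymes, 10 rose and 1 fell in control leaves, 27 did not pass, and 12 passed when adjusted over the list alone. GSTU42 rose at least 3.38-fold (measured log2 2.77 ± 0.57, adjusted p = 0.00751, and log2 3.38 and 2.16 without control 48 h replicates 1 and 2) and GSTU26 (LOC547578) 3.98-fold (1.99 ± 0.30, 0.0019). The list was higher by camera (adjusted p = 0.0165, and adjusted p = 0.647 with an estimated correlation). Cytochrome P450 genes gave 9 rises, 1 fall and 22 that did not pass of 32, with 12 passing when adjusted over the list alone. CYP82A2 rose at least 1.91-fold (measured log2 2.27 ± 0.40, and 2.86 without control 48 h replicate 3), CYP82A4 (LOC100778056) at least 2.87-fold and CYP81E11 at least 1.01-fold. Their list was higher by camera at adjusted p = 0.022 (adjusted p = 0.549 with an estimated correlation), and it lost the call without control 48 h replicate 1 (0.0557, in a range of 0.000779 to 0.0557 over 10 alternatives). Other genes with large rises were SMEP1, which encodes a metalloproteinase (7.11-fold, and 3.99-fold without control 0 h replicate 3), and SIK2 (5.28-fold, log2 2.40 ± 0.20). The gene with the symbol H4 rose 13.9-fold (3.79 ± 0.27). That symbol stands for a histone in 1 use and for a stress-induced protein related to SAM22 in another, and of the 8 genes in the list of cell cycle and histones, H4 alone passed.

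Of the 26 genes of the cold response, 6 fell in control leaves, 1 rose and 19 did not pass, and 8 passed when adjusted over the list alone. The CBF transcription factor gene DREB1-like fell at least 2.39-fold (measured log2 −2.34 ± 0.30, adjusted p = 0.000736), the cold-regulated gene SRC2 3.64-fold (−1.86 ± 0.17, 7.28e-05) and COR2 2.24-fold (−1.17 ± 0.15, 0.000809). The list was lower by camera (adjusted p = 0.022, and adjusted p = 0.460 with an estimated correlation). Of 13 ethylene genes, 5 fell, 2 rose and 6 did not pass, with 9 passing when adjusted over the list alone, and the set did not pass (adjusted p = 0.342). Beside ACS1, the ethylene response factor genes EBP and ERF6 fell 3.91-fold and 3.18-fold, and the receptor gene ETR2 rose at least 1.32-fold.

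The wall-loosening enzyme gene XTH1 fell 6.42-fold in control leaves (log2 −2.68 ± 0.18, adjusted p = 1e-05). GASA11 and GASA3, genes of gibberellin-stimulated peptides, fell 9.45-fold (−3.24 ± 0.59) and 7.85-fold (−2.97 ± 0.39), and the fall of GASA11 was 4.88-fold without control 48 h replicate 2 and 14.3-fold without replicate 3. The allene oxide cyclase gene AOC4, of jasmonate synthesis, fell at least 4.59-fold (measured log2 −2.83 ± 0.33, 0.00037). B13-1-9 fell 13.4-fold, and the transcription factor genes BZIP50 and BZIP48 fell 5.73-fold and 5.11-fold, each to a level above background on 1 of 3 arrays. Of 18 genes of cell wall remodelling 5 fell, 2 rose and 11 did not pass, with 7 passing when adjusted over the list alone, and the set did not pass (camera adjusted p = 0.319). NAC018 fell 4.75-fold (−2.25 ± 0.53, 0.0138), a call lost without control 0 h replicate 3 (log2 −2.02, adjusted p = 0.0521, in a range of 0.00265 to 0.0521 over its alternatives).

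Of 8 genes of ribosomal proteins and translation, 3 fell in control leaves, 5 did not pass, and 5 passed when adjusted over the list alone. RPS13, RPL2 and p40 (LOC548014) fell by 0.48, 0.38 and 0.39 on the log2 scale. The other probe sets of RPS13 and RPL2 differed by −0.32 each and did not pass. The list was lower by camera at adjusted p = 0.0478 (adjusted p = 0.647 with an estimated correlation). The call was lost with the replicate number as a block (0.0609) and without control 0 h replicate 1 (0.0656) or 3 (0.0843) or control 48 h replicate 1 (0.126) or 3 (0.0528), in a range of 0.00131 to 0.126. Soybean rRNA probe sets, a quality measure and no test of this list, were lower at 48 h by a mean log2 difference of −0.372 over both sprays. The exact permutation p was 0.0455 (two-sided, 6 against 6 arrays, not adjusted), and 0.2 within each spray (3 against 3).

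**Figure D2:**
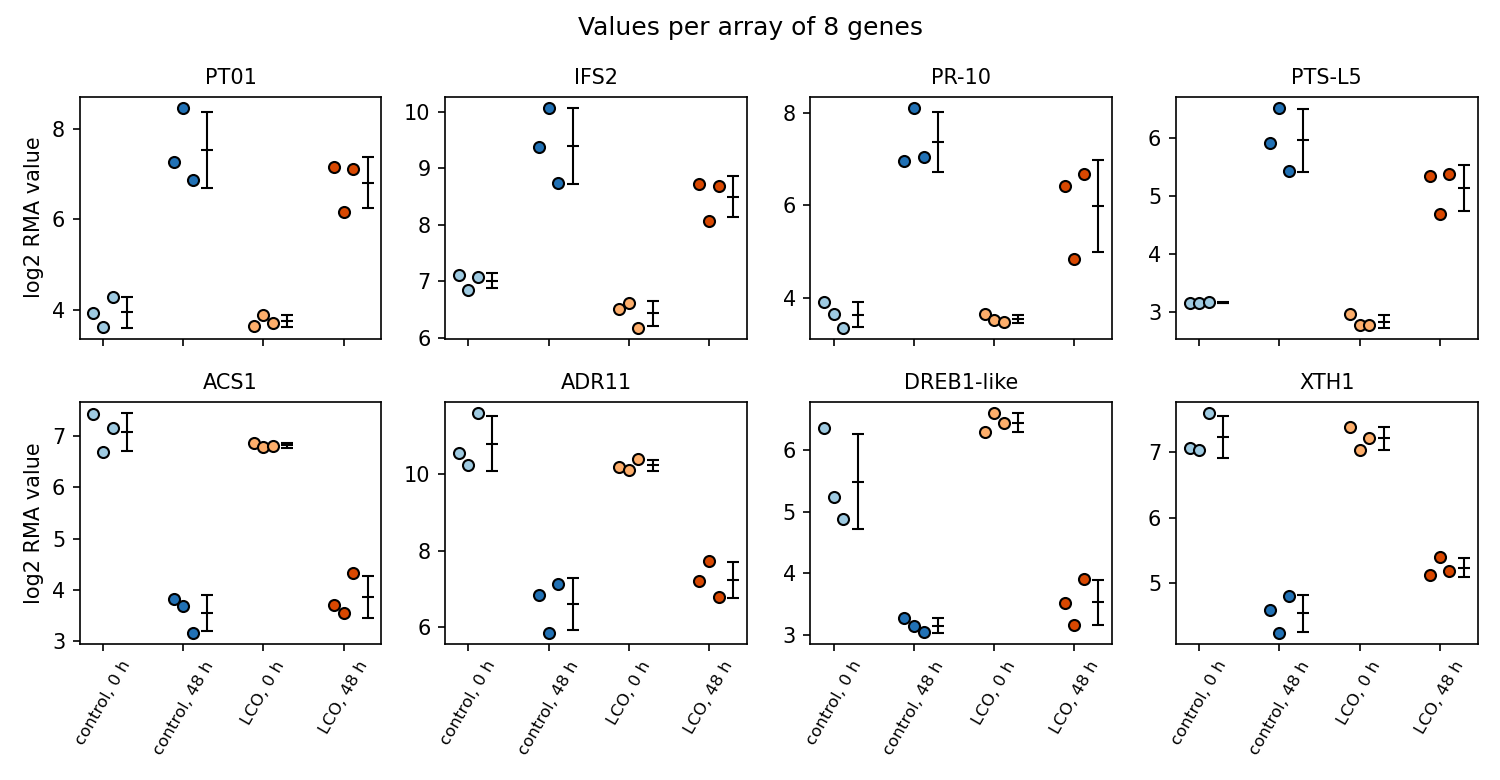
Log2 RMA values (y axes) of 8 genes in the 4 groups (x axes), each point an array and each bar the group mean ± SD of 3 arrays; the genes drawn were chosen after their values were seen. PT01, IFS2, PR-10 and PTS-L5 lie higher at 48 h than at 0 h on all arrays of both sprays, and ACS1, ADR11, DREB1-like and XTH1 lie lower.

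In LCO leaves several of these genes also changed over the 48 h. SGlu5 (LOC547748) rose 9.18-fold (log2 3.20 ± 0.35, n = 3 and 3, limma adjusted p = 0.000304), PT01 at least 5.53-fold (measured log2 3.05 ± 0.36, 0.000573) and PR-10 at least 3.11-fold (2.43 ± 0.41, 0.00573). ACS1 fell at least 3.37-fold (−3.17 ± 0.23, 2.8e-05), by a probe set other than the one named for control leaves, which fell by 2.96 on the log2 scale. ADR11 fell 7.90-fold (−2.98 ± 0.37) and DREB1-like at least 4.38-fold (−2.92 ± 0.30). In total 1001 probe sets rose and 1066 fell, 277 and 485 of them at least 2-fold, and the median log2 difference was 0.00. The count of 2067 fell to 995, 1376 and 993 without LCO 0 h replicates 1, 2 and 3, and to 791 and 1196 without LCO 48 h replicates 1 and 3. With array weights it was 6387, above the 5619 of control leaves in the same fit, so that the order of the sprays turned. When only the groups compared were fitted it was 2706, against 3496 in control leaves. The median SD of a probe set at 0 h and 48 h was 0.149 and 0.143 in control leaves and 0.117 and 0.133 in LCO leaves. The main fit shares 1 estimate of the spread, so the counts of the sprays depend on how the spread is estimated.

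Of the 46 genes of isoflavonoid and phenylpropanoid synthesis, 14 rose in LCO leaves and 32 did not pass, and 22 passed when adjusted over the list alone. IFS2 rose 4.19-fold (log2 2.07 ± 0.28, adjusted p = 0.00121), DIR22 3.30-fold (1.72 ± 0.18, 0.000282) and CHS8 5.35-fold by 1 probe set (2.42 ± 0.31) and 3.90-fold by another. A dimmer probe set of CHS8, still above background, had a log2 difference of 0.78 that did not pass (adjusted p = 0.0737). The isoflavone reductase gene IFR (LOC547659) rose at least 1.45-fold and PTS-L5 at least 1.73-fold. The list was higher by camera (adjusted p = 6.73e-08, and adjusted p = 0.203 with an estimated correlation). Among 11 genes of UDP-glycosyltransferases and saponin synthesis, 1 rose and 10 did not pass, and 7 passed when adjusted over the list alone. The isoflavone 7-O-glucosyltransferase gene IF7GT was the 1 that rose (0.62 ± 0.11, 0.00783), and this list was higher at adjusted p = 0.000987 (adjusted p = 0.203 with an estimated correlation).

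Pathogenesis-related proteins gave 5 rises and 11 genes that did not pass of 16 in LCO leaves, with 8 passing when adjusted over the list alone. CHIA1 rose at least 2.76-fold (measured log2 1.81 ± 0.26, adjusted p = 0.00207), and the set was higher (adjusted p = 0.000987, and adjusted p = 0.203 with an estimated correlation). Of 32 cytochrome P450 genes 2 rose and 30 did not pass, with 5 passing when adjusted over the list alone, and the set was higher (adjusted p = 0.0024, and adjusted p = 0.203 with an estimated correlation). CYP82A4 (LOC100778056) had a log2 difference of 1.41 that did not pass. Of 38 glutathione S-transferase genes 3 rose, 1 fell and 34 did not pass, with 7 passing when adjusted over the list alone. Their set was higher at adjusted p = 0.0258 (adjusted p = 0.468 with an estimated correlation), a call lost with all probe sets of the genes (0.0707) and without LCO 0 h replicate 1 (0.0593) or 2 (0.0868), in a range of 0.00332 to 0.0868. SMEP1 rose 5.21-fold (2.38, 0.0289), and lost the call with a trended and robust variance prior (0.0586) and in 5 of the 6 fits that left out an array of this spray. The adjusted p was 0.0826, 0.0526 and 0.11 without LCO 0 h replicates 1, 2 and 3 and 0.11 and 0.0965 without LCO 48 h replicates 1 and 3, in a range of 0.000764 to 0.11.

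In LCO leaves 4 of the 26 genes of the cold response fell and 22 did not pass, with 4 passing when adjusted over the list alone, and the list was lower by camera (adjusted p = 0.0108, and adjusted p = 0.203 with an estimated correlation). SRC2 fell 3.14-fold (log2 −1.65 ± 0.17, adjusted p = 0.000199) and COR2 1.92-fold (−0.94 ± 0.15, 0.00435) beside DREB1-like. The WRKY transcription factor genes WRKY46, WRKY27 and WRKY43 fell 9.68-fold (−3.28 ± 0.37, 0.000389), 6.81-fold (−2.77 ± 0.51, 0.00905) and 4.38-fold (−2.13 ± 0.22, 0.00024). Of the 53 WRKY genes 10 fell, 1 rose and 42 did not pass, 17 passed when adjusted over the list alone, and the set did not pass (0.0632). AOC4 fell 5.37-fold, NAC69 (LOC100814504) 4.62-fold and B13-1-9 10.0-fold (−3.32 ± 0.47, 0.00161), each to a level above background on 1 of 3 arrays.

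Of 30 genes of gibberellin, cytokinin and brassinosteroid, 4 fell in LCO leaves and 26 did not pass, and 5 passed when adjusted over the list alone. GASA3 fell 5.34-fold (log2 −2.42 ± 0.39, adjusted p = 0.00378). The list was lower at adjusted p = 0.0427 (adjusted p = 0.439 with an estimated correlation). It lost the call with quantile normalization (0.0585) and without LCO 0 h replicate 1 (0.0531) or 2 (0.0756) or LCO 48 h replicate 1 (0.0566) or 2 (0.114), in a range of 0.00296 to 0.114. Of 20 phosphate starvation genes 2 rose and 18 did not pass, and 4 passed when adjusted over the list alone. The acid phosphatase gene PAP25 rose 2.28-fold (1.19 ± 0.21, 0.00788). This list was higher at adjusted p = 0.0427 (adjusted p = 0.456 with an estimated correlation) and lost the call with quantile normalization (0.0653) and without LCO 0 h replicate 2 (0.0996) or LCO 48 h replicate 1 (0.0549) or 2 (0.114), in a range of 0.00209 to 0.114. The 8 genes of ribosomal proteins and translation gave 1 fall, of p40, which did not pass after median centring, and 7 that did not pass, with 1 passing when adjusted over the list alone. That list was lower at adjusted p = 0.0258 (adjusted p = 0.456 with an estimated correlation), lost without LCO 48 h replicate 3 (0.0885, in a range of 0.00209 to 0.0885).

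**Figure D3:**
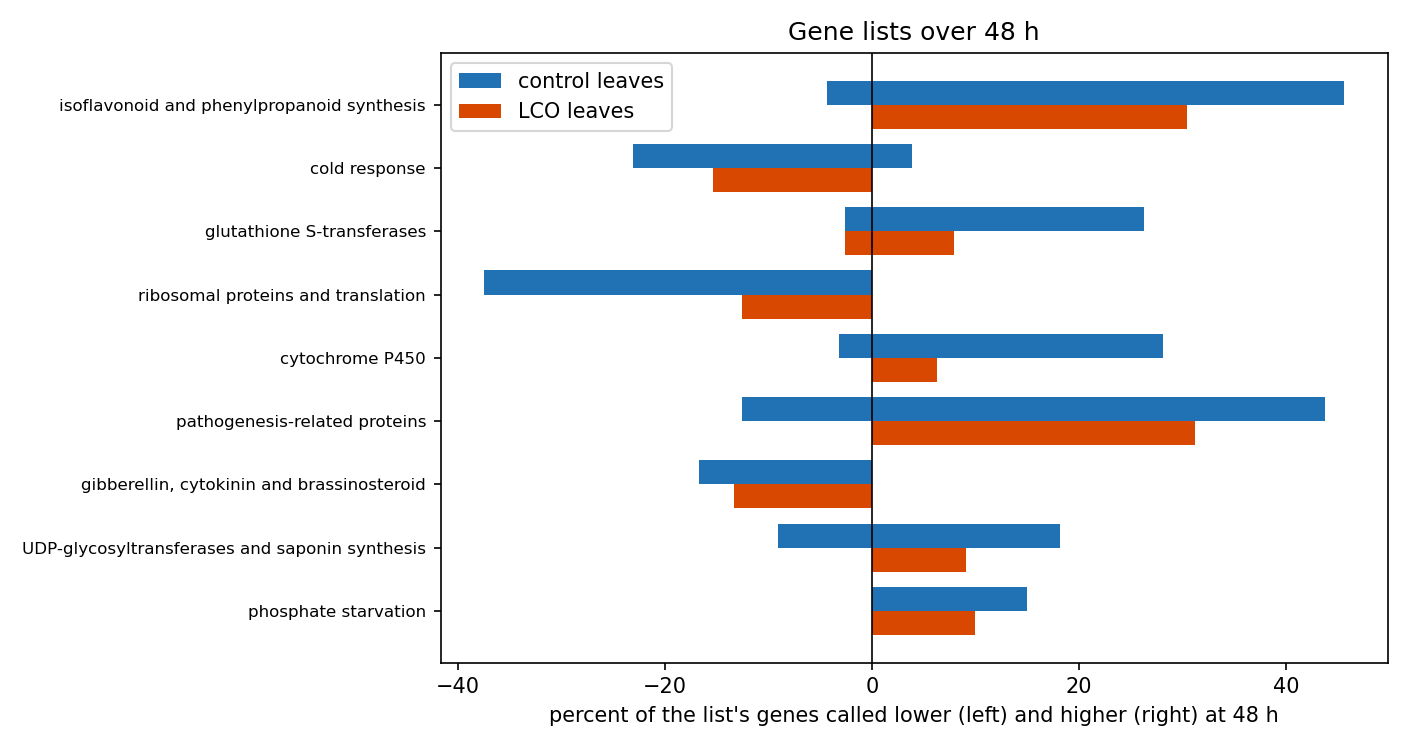
Percent of the genes of each list (x axis) called lower (left of 0) and higher (right of 0) at 48 h against 0 h in control and LCO leaves (bars), for the 9 lists that camera called in at least 1 spray. Isoflavonoid and phenylpropanoid synthesis had 21 and 14 of 46 genes higher, and the cold response had 6 and 4 of 26 lower.

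The changes over time in the sprays share no array, and their log2 values correlated across the soybean probe sets at Pearson r = 0.847 and Spearman ρ = 0.727, where genes are not independent replicates. The same correlation across the probe sets of Phytophthora sojae and Heterodera glycines, soybean pathogens whose probe sets measure background here, was 0.030 and 0.014. Of the 1001 probe sets that rose in LCO leaves, 808 also rose in control leaves, and 880 of the 1066 that fell also fell. Independent lists of these sizes would share 89.3 and 97.5. No probe set (0) was called in opposite directions by limma. Among the 6792 probe sets called in control leaves, 97.4% had the same sign in LCO leaves, with a median change along that sign of 0.39 against 0.63 in control leaves. Among the 2067 called in LCO leaves the medians were 0.82 in LCO and 0.80 in control leaves, and each set is favoured by the spray in which it was chosen.

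Whether LCO altered the change over time was tested by the interaction of spray and time. PR-10 rose at least 8.71-fold in control and at least 3.11-fold in LCO leaves, and the difference of the measured changes, −1.30 on the log2 scale, did not pass. WRKY46 fell 3.93-fold and 9.68-fold, an interaction of −1.30 ± 0.52, and it did not pass either. GASA11 had an interaction of 1.57 and ADR11 of 1.19, and neither passed. No soybean probe set (0 of 37593) passed by limma, with a smallest adjusted p of 0.392 and 1642 probe sets (4.37%) at an unadjusted p under 0.05. Without control 0 h replicate 2 the count was 1. The 6 genes with the smallest p in each direction did not pass (adjusted p = 0.966). They were led by the glycosyltransferase gene UGT78K1 (0.80 ± 0.17, unadjusted p = 0.000595) and the peroxidase gene PRX2 (0.51 ± 0.11). On the lower side ETR2 came first, which was above background in control leaves at 48 h and in no other group, then WRKY23, by a probe set below background in all 4 groups, and then the receptor-like kinase gene CRK39 (−0.81 ± 0.24). In simulated data 7.46% of 1.5-fold, 58.2% of 2-fold and 97.0% of 4-fold interactions were recovered.

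Of the 53 WRKY genes and the 31 genes of immune receptors and signalling, 0 passed the interaction by limma, over all genes or when adjusted over the list alone, and 3 and 1 had an unadjusted p under 0.05. As sets both were lower in their interaction by camera, with medians of −0.09 and −0.12 and adjusted p = 0.0246 and 0.0425 (adjusted p = 0.759 with an estimated correlation for each). The WRKY call was lost without control 0 h replicate 3 (0.198), control 48 h replicate 2 (0.0594), LCO 0 h replicate 1 (0.0793) or 3 (0.0579), or LCO 48 h replicate 2 (0.0638), in a range of 7.66e-05 to 0.198. The immune call was lost with all probe sets (0.0912), without control 0 h replicate 1 (0.217) or 3 (0.0567), control 48 h replicate 2 (0.0594) or 3 (0.063), LCO 0 h replicate 1 (0.102) or 3 (0.0579), or LCO 48 h replicate 2 (0.223), in a range of 0.0044 to 0.223.

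**Figure D4:**
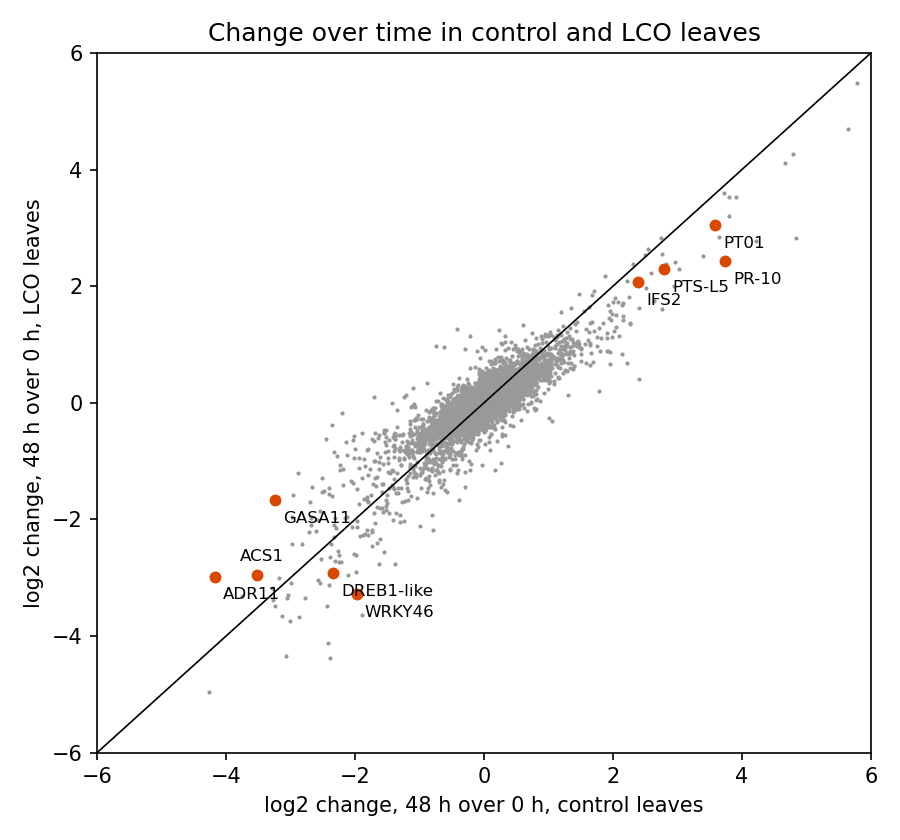
Log2 change from 0 h to 48 h in control leaves (x axis) and LCO leaves (y axis) for the soybean probe sets with 1 gene symbol (grey points), with the line of equal change and 9 labelled genes chosen after their values were seen. PT01 and PR-10 lie at 3.58 and 3.73 on the x axis and ADR11 at −4.17, and no probe set passed the test of the interaction.

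Levels in LCO leaves were set against control leaves at 48 h across what appear to be separate normalization runs. DD2/63 was at least 3.24-fold higher in LCO leaves (measured log2 1.90 ± 0.17, n = 3 and 3, limma adjusted p = 9.62e-05), the expansin gene EXP4 3.21-fold (1.68 ± 0.24, 0.00111) and the galactolipid synthase gene DGD2 at least 1.32-fold (1.49 ± 0.12, 6.22e-05). The brightest of the 4 probe sets of DGD2 differed by −0.14 and did not pass. GSTU17 was 2.50-fold higher, and the alanine aminotransferase gene ALAAT1 2.17-fold by 1 probe set, while its other differed by 0.29 on the log2 scale and did not pass. Lower in LCO leaves were the bZIP genes STF2 (3.08-fold, −1.62 ± 0.18, 0.000324) and BZIP36 (3.03-fold, −1.60 ± 0.15, 0.000144), GASA6 (3.03-fold) and WRKY46 (3.05-fold, −1.61 ± 0.37, 0.0106). WRKY51 was 2.81-fold lower and CYP82A3 2.63-fold, each above background on 1 of 3 LCO arrays. Part of these differences was already present at 0 h. The 0 h means in control and LCO leaves were 5.49 and 4.57 for STF2, 6.88 and 5.81 for BZIP36, and 9.58 and 8.58 for GASA6. They were 10.39 and 11.15 for EXP4, and lay closer for WRKY46 at 8.49 and 8.19. At 48 h GASA11 was 4.05-fold higher (2.02 ± 0.59, 0.0308), and 2.09-fold without control 48 h replicate 2 and 6.13-fold without replicate 3. It was a call lost when only the groups compared were fitted (0.0807), with a trended and robust variance prior (0.0581), and without LCO 48 h replicate 1 (0.0606), 2 (0.0978) or 3 (0.0568), in a range of 0.0118 to 0.0978 over its alternatives. PR-10 was 2.62-fold lower (−1.39 ± 0.41, 0.0318), a call lost without control 48 h replicate 2 (−1.02, 0.125) or LCO 48 h replicate 2 (−0.82, 0.0863) and when only the groups compared were fitted (0.0848), in a range of 0.0175 to 0.125. The other probe set of PR-10 differed by −0.43 and did not pass. The largest fall among the named genes was that of SCOF-1 (3.14-fold, −1.65 ± 0.42, 0.0161). Its call was lost without control 48 h replicate 2 (0.0562) or LCO 48 h replicate 2 (0.0666).

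At 48 h 8547 soybean probe sets differed between the sprays, 2073 higher and 6474 lower in LCO leaves, and 188 and 476 of them at least 2-fold. The median soybean value of the LCO arrays differed from that of the control arrays by −0.159 over both times (exact permutation p = 0.00216, two-sided, 6 against 6 arrays), and the median log2 difference was −0.09. After quantile normalization over soybean probe sets the split was 3346 higher and 3558 lower, and after median centring 4769 and 2678, so directions here hold relative to that shift. Of the 23350 pathogen probe sets, 2673 (11.4%) also differed between the sprays. The count of 8547 fell to 4833 without control 48 h replicate 2 and to 5596 and 4866 without LCO 48 h replicates 1 and 2. The difference between the 3′ and 5′ probe sets was larger by 0.317 for actin on the LCO arrays (exact permutation p = 0.0108, two-sided, 6 against 6) and that of glutathione transferase differed by −0.783 (p = 0.00216). Another pair of actin probe sets differed by −0.0353 (exact permutation p = 0.773) and ubiquitin by −0.118 (p = 0.201).

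Of the 67 bZIP transcription factor genes 25 were lower in LCO leaves at 48 h and 42 did not pass, with 29 passing when adjusted over the list alone; after quantile normalization or median centring 3 were higher and 16 lower. BZIP69 and BZIP54 had log2 differences of −1.18 and −0.84 beside STF2 and BZIP36. The list was lower at adjusted p = 0.0278 (adjusted p = 0.848 with an estimated correlation), a call lost without control 48 h replicate 2 (0.0585, in a range of 0.0229 to 0.0585). Of 20 genes of photosystem, carbon fixation and tetrapyrroles, 4 were higher in LCO leaves and 16 did not pass, with 4 passing when adjusted over the list alone. RCA11, for an activase of Rubisco, was 1.91-fold higher (log2 0.93 ± 0.10, adjusted p = 0.000293). The list was higher at adjusted p = 0.0278 (adjusted p = 0.848 with an estimated correlation), lost with quantile normalization (0.149) and without control 48 h replicate 2 (0.0585) or LCO 48 h replicate 2 (0.0578), in a range of 0.0105 to 0.149. Of 22 genes of the jasmonate and lipoxygenase pathway 2 were higher and 20 did not pass, and 0 passed limma when adjusted over the list alone, where 5 had an unadjusted p under 0.05. The vegetative storage protein gene VSPB (LOC547820) was higher by 1.04 on the log2 scale (adjusted p = 0.0259) by 1 of its 3 probe sets, while the others, with means of 2.68 and 2.83 that lie below the background limit, differed by −0.02 and −0.01. Its call was lost with array weights (0.081), when only the groups compared were fitted (0.0693), and without control 48 h replicate 1 (0.0907) or 2 (0.0541) or LCO 48 h replicate 2 (log2 0.65, 0.0741), in a range of 0.007 to 0.0907. That list was higher at adjusted p = 0.0278 (adjusted p = 0.848 with an estimated correlation), lost with quantile normalization (0.124) and without control 48 h replicate 1 (0.0724) or 3 (0.0934) or LCO 48 h replicate 2 (0.0578), in a range of 0.00621 to 0.124.

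Leaves taken directly after the spray differed between LCO and control too, again across what appear to be separate runs. This comparison was planned as a measure of how far the leaves differed before a transcript response could build up. DD2/63 was 3.14-fold higher in LCO leaves at 0 h by 1 probe set (log2 1.65 ± 0.17, n = 3 and 3, limma adjusted p = 0.000324), and its other, brighter probe set differed by −0.03 and did not pass. DGD2 was at least 1.11-fold higher by the probe set named at 48 h (measured log2 1.5 ± 0.12, 0.000151), while its brightest differed by −0.18 and did not pass, and the inositol phosphate kinase gene ITPK3 was 2.80-fold higher (1.49 ± 0.25, 0.00331) by 1 of 5 probe sets. The brightest probe set of ITPK3 differed by 0.34 and did not pass. WRKY51 was at least 1.66-fold lower (measured log2 −1.41 ± 0.16, 0.000551), CYP82A3 at least 1.82-fold (−1.40 ± 0.28, 0.00737), NAC19 at least 1.90-fold (−1.39 ± 0.19, 0.00113) and the gibberellin oxidase gene GA20OX3 at least 1.33-fold. A brighter probe set of CYP82A3 differed by −0.71 and did not pass. Of these genes, DD2/63, DGD2, WRKY51 and CYP82A3 were also named at 48 h, and their interactions were 0.25, −0.01, −0.09 and 0.00. ALAAT1 was 1.85-fold higher at 0 h by the probe set named at 48 h (0.89 ± 0.16, adjusted p = 0.00398), with an interaction of 0.23. DREB2A2 was 2.08-fold higher (1.06 ± 0.25), from a control level above background on 1 of 3 arrays, a call lost without LCO 0 h replicate 1 (0.88, adjusted p = 0.0632, in a range of 0.0065 to 0.0632).

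At 0 h 6524 soybean probe sets differed, 1575 higher and 4949 lower in LCO leaves, with a median log2 difference of −0.08. The split was 2331 higher and 2476 lower after quantile normalization and 3332 and 2073 after median centring. The count was 4133 without LCO 0 h replicate 1 and 3187 without replicate 3. Among pathogen probe sets 2532 (10.8%) differed. The spray differences at 0 h and 48 h share no array and correlated at Pearson r = 0.746 (ρ = 0.728) across soybean and 0.725 (0.670) across pathogen probe sets. Of the probe sets higher in LCO leaves at 0 h, 978 of 1575 were higher at 48 h, and of the lower ones 3515 of 4949 were lower, where independent lists would share 86.9 and 852. No gene list (0 of 34) passed by camera at 0 h, with a smallest adjusted p of 0.0749 and 8 lists at an unadjusted p under 0.05. The bZIP list had 21 genes lower and 46 that did not pass, 24 passing when adjusted over the list alone, with 1 higher and 14 lower after quantile normalization and 1 and 12 after median centring.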

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

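Of the tests given here, those on the labelling spikes and on the range of values, and the ratio of the time responses itself, were chosen only after the results were seen.

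Probe sets of Phytophthora sojae and Heterodera glycines drew attention because 2673 of 23350 differed between LCO and control leaves at 48 h and 2532 at 0 h, although they measure background in these leaves. Over time 2 and 1 of them were called in control and LCO leaves, while their spray differences at 48 h and at 0 h, which share no array, correlated at r = 0.725, and separate RMA runs may therefore account for part of the spray difference in soybean probe sets too. A leaf response to LCO that grows with time would raise the number of soybean calls from 0 h to 48 h. The counts stood at a ratio of 1.31. Its range of 0.741 to 2.68 sets a count without 1 array against a full count, so it cannot judge the ratio. Growth of the spray difference is what the interaction of spray and time tests. There limma called 0 of 37593 soybean probe sets, with 1642 (4.37%) at an unadjusted p under 0.05. No growth was therefore seen in single probe sets, in a test that recovered 7.46% of simulated 1.5-fold and 58.2% of 2-fold interactions. Growth of 1.5-fold would thus mostly be missed. Labelling spikes averaged 6.70 on LCO and 7.07 on control arrays at 0 h (exact permutation p = 0.1, the smallest that 3 against 3 allow) and 7.05 and 6.98 at 48 h (p = 0.7), against a difference of −0.152 over both times (p = 0.277, 6 against 6). They therefore showed no equal difference at both times, yet a batch of labelling or hybridisation and an RMA run cannot be told apart, because both would coincide with the spray.

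The change over time looked smaller in LCO than in control leaves. The slope of the change in LCO leaves on that in control leaves, corrected for the error of the latter, was 0.834, with a jackknife SE of 0.171 and a range of ± 2 SE from 0.493 to 1.18 that includes 1. A narrower range of the LCO values could shrink all changes, and the mean SD of an array's values was 0.976 times that of control arrays. A single array could carry it, since without control 48 h replicate 2 the slope was 0.985. After quantile normalization, which gives all arrays the same distribution of soybean values, the slope was 0.841. A difference in the range of an array's values therefore accounts for little of the estimate. A weaker response after LCO and 1 array cannot be told apart at this precision.

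The set of 53 WRKY genes and the set of 31 genes of immune receptors and signalling drew attention because their change over time was lower in LCO than in control leaves (camera adjusted p = 0.0246 and 0.0425), while 0 genes of either passed limma, with 3 and 1 at an unadjusted p under 0.05. With the correlation estimated neither set passed by camera (adjusted p = 0.759 for each), so chance was not excluded as their source. Of 100 regroupings of the times within sprays, 68 called as many lists as the real one (2, highest other 9). Such regroupings mix 0 h and 48 h arrays, so changes over time can enter their interaction. Their share therefore cannot decide how far chance accounts for these sets. For single probe sets limma called 0 (1642 at an unadjusted p under 0.05), a number that all 100 regroupings reach by construction (highest other 1), so they decide nothing.

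The difference between 3′ and 5′ actin probe sets was 0.317 larger on LCO than on control arrays (exact permutation p = 0.0108, 6 against 6), and that of glutathione transferase differed by −0.783 (p = 0.00216), while another pair of actin probe sets differed by −0.0353 (p = 0.773) and ubiquitin by −0.118 (p = 0.201). Soybean rRNA probe sets differed by −0.372 between 48 h and 0 h (exact permutation p = 0.0455, 6 against 6, and 0.2 within each spray, 3 against 3). None of these p-values was adjusted for the number of measures compared.

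For the correlation of the time changes between the sprays 1 of 100 regroupings, the real one, was as high (0.847, highest other 0.709). The other regroupings mix 0 h and 48 h arrays and keep part of the change over time. None of those drawn reached the correlation of the real times, which is all that this test shows. For the contrasts of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real split called 8547 probe sets between sprays at 48 h (highest other 0), 6524 at 0 h (19), 6792 over time in control leaves (0) and 2067 in LCO leaves (1), and in each case 1 split reached the real count. For gene lists the real splits called 3 at 48 h (highest other 5), 0 at 0 h (5), 5 in control leaves (6) and 9 in LCO leaves (7), and 4, 10 (by construction at 0), 5 and 1 of the 10 splits reached these numbers. Every other split mixes the groups compared and keeps part of the real difference between them. These numbers are therefore no clean measure of chance. Of the control splits, 3 others part all same-numbered pairs as the real one does, and they called 1 to 6 lists, against 1 to 5 for the 6 that part fewer.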

How the results depend on the processing

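The replicate block within each spray and the alternatives of the slope were chosen after the data were seen. With a 2-fold threshold added the counts of called probe sets were 664 for LCO against control at 48 h, 380 at 0 h, 1402 over time in control leaves and 762 in LCO leaves, and at an unadjusted p under 0.05 they were 13862, 12244, 12129, 8048 and, for the interaction, 1642, both by construction. Unadjusted p with 1.5-fold gave 3941, 2900, 4404 and, for the interaction, 534. Leaving out 1 array gave 4833 to 7465, 3187 to 5284, 3120 to 6413, 791 to 2167 and 0 to 1. Only the groups compared gave 3496 in control leaves and 2706 in LCO leaves, array weights gave 6387 in LCO leaves, and the cause was not tested. At 48 h 2073 were higher and 6474 lower, against 3346 and 3558 after quantile normalization and 4769 and 2678 after centring; at 0 h 1575 and 4949, against 2331 and 2476, and 3332 and 2073. The correlation of the time changes was 0.868 without dim probe sets and 0.80 to 0.861 without 1 array. The pathogen probe sets' 95th percentile differed by 0.0894 between sprays, their median by 0.0371. Called lists numbered 3, 0, 5, 9 and 2 in the same order: with all probe sets 7 at 48 h, 2 at 0 h, 10 in control leaves and 6 for the interaction; with an estimated correlation 0 in each by camera; with quantile normalization 1 at 48 h; without 1 array 1 to 4, 0 to 3, 3 to 7, 7 to 12 and 0 to 4. With the replicate number as a block the counts were 7664, 5649, 6336, 1805 and 0, and within each spray 7560 in control leaves, 2763 in LCO leaves and 0. Lists under the block numbered 3, 0, 4, 9 and 3 and within each spray 4, 10 and 3; the call of the ribosomal list in control leaves (adjusted p = 0.0609 with the block, 0.0835 within each spray), of PR-10 between sprays at 48 h (0.0521, in a range of 0.0175 to 0.125) and of HS1pro1 in LCO leaves (0.0694, in a range of 0.00179 to 0.164) ended, the list of senescence and NAC factors passed in the interaction (0.0468, and 0.0072 within each spray, against 0.0543 without a block and adjusted p = 0.759 with an estimated correlation), the WRKY list passed in LCO leaves within each spray (0.0191, against 0.0632 without a block and adjusted p = 0.669 with an estimated correlation), and the block changed no other call of a named gene or list in these contrasts. In LCO leaves the pairing check gave r = −0.03, 0.136 and 0.003, between sprays −0.106, −0.138 and 0.09 at 0 h and −0.125, −0.251 and −0.206 at 48 h. In each at most 2 of 6 samples correlated best with their own number, so no pairing was seen. What samples of a number share cannot be told from these values. Of 528 values of named genes that passed, 478 kept direction and call without 1 array, 50 lost the call and 0 reversed, and of 658 under other settings 637, 21 and 0. Signal over background limits dim genes: 25856 of 37593 probe sets lay above 4.23, the 95th percentile of the pathogen probe sets.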

Other observations

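No test in this part was chosen after the results were seen, apart from the bounds on folds over the background limit.

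Several gene lists not described so far held members that changed over time, though none of these lists passed as a set in either spray. Of 40 genes of abscisic acid and dehydration, 3 fell, 2 rose and 35 did not pass in control leaves, and 4 fell and 36 did not pass in LCO leaves (camera adjusted p = 0.816 and 0.172), with 4 passing in each when adjusted over the list alone. The dehydrin gene MAT1 fell 4.36-fold in control leaves (log2 −2.13 ± 0.16, SE, n = 3 and 3, limma adjusted p = 2.29e-05) and 3.89-fold in LCO leaves (−1.96 ± 0.16, 5.65e-05), to levels above background on 1 and 2 of 3 arrays. Of 24 genes of calcium signalling, 3 fell in control and 2 in LCO leaves and 21 and 22 did not pass (0.756 and 0.258), with 3 and 2 passing when adjusted over the list alone. The calcium pump gene SCA1 fell 3.5-fold and 3.26-fold. Among 23 aquaporin genes 5 fell, 1 rose and 17 did not pass in control leaves, and 1 rose and 22 did not pass in LCO leaves (0.294 and 0.621), with 7 and 3 passing when adjusted over the list alone. PIP1-6 fell 3.05-fold in control leaves (−1.61 ± 0.33), and PIP2-2 rose 1.61-fold in control and 1.54-fold in LCO leaves. Of 27 genes of senescence and NAC factors 5 rose, 2 fell and 20 did not pass in control leaves, and 2 rose, 2 fell and 23 did not pass in LCO leaves (0.319 and 0.857), with 10 and 6 passing when adjusted over the list alone. SGR1 and SGR2, stay-green genes of chlorophyll breakdown, rose 2.28-fold and 3.47-fold in control leaves. Of 30 genes of heat shock proteins and chaperones 5 rose and 25 did not pass in control leaves, and 3 rose and 27 did not pass in LCO leaves (0.263 and 0.586), with 5 and 4 passing when adjusted over the list alone. The heat shock factor gene HSF-01 rose 2.43-fold and 2.33-fold by its brighter probe set and fell by 0.87 and 0.98 on the log2 scale by the other, and the chaperone gene BIP4 of the endoplasmic reticulum 2.28-fold in control leaves.

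LCOs are signals for nodulation, and of 29 nodulation genes 2 rose, 3 fell and 24 did not pass over time in control leaves, with 5 passing when adjusted over the list alone. In LCO leaves 1 rose and 28 did not pass, with 2 passing over the list alone, and the list passed in neither spray (camera adjusted p = 0.342 and 0.635). The 1 that rose in LCO leaves, NF-YA05, rose in control leaves as well (log2 0.65 and 0.59, limma adjusted p = 0.00531 and 0.0169). Its call in LCO leaves was lost without LCO 0 h replicate 2 or 3 or LCO 48 h replicate 1, with log2 values of 0.54 to 0.64 over the fits without 1 array. At 48 h 2 nodulation genes were higher and 5 lower in LCO than in control leaves, across what appear to be separate normalization runs, against 2 and 4 after quantile normalization and 4 and 3 after median centring (camera adjusted p = 0.783). FWL8 was at least 1.72-fold lower (measured log2 −1.15 ± 0.15) and NARK, a receptor kinase gene of nodule number control, differed by −0.90 ± 0.18, and both passed under each scaling. Among 23 markers of nodules and seeds 2 rose and 21 did not pass in control leaves, led by the proteinase inhibitor gene BBI-1 (at least 1.19-fold, above background on 1 of 3 arrays at 48 h), and all 23 did not pass in LCO leaves, 3 with an unadjusted p under 0.05 by limma. Over time the 17 markers of phloem and sieve elements did not pass in either spray, 2 in each with an unadjusted p under 0.05, and 1 rose in LCO leaves after quantile normalization or median centring. Between the sprays 0 of them were higher and 3 lower in LCO leaves at 48 h, against 1 and 2 after quantile normalization and 2 and 2 after median centring, with 2 passing when adjusted over the list alone. At 0 h 1 was higher and 3 were lower, against 1 and 2 after either scaling, with 4 passing over the list alone (camera adjusted p = 0.943 at 48 h and 0.913 at 0 h). Of 12 housekeeping genes 1 rose, 1 fell and 10 did not pass in control leaves, and 12 did not pass in LCO leaves, 1 with an unadjusted p under 0.05.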
